A study of Mus musculus with 12 samples.

How the data were processed

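Cortical DNA from C57BL/6 mice was sequenced after bisulfite conversion, and 12 deposited tables, one per library, were analysed. Per the labels' protocols, cortical DNA was sonicated, spiked with unmethylated lambda DNA to follow conversion, and bisulfite sequenced; conversion rates were not used here. Per the submitters' processing notes, reads were processed with BSMAP on the mm9 genome, with no version given. Each table the authors deposited lists RefSeq transcripts with a whole-number count of methylated non-CG calls and an expected count of total calls. The total is often not whole (35.7% to 62.2% of values are), and how it was derived is not given in the sources used here. Totals were rounded to whole numbers, and the level is methylated calls over total calls, in percent.

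Of 36672 rows per table, 300 had no symbol in the RefSeq table of assembly GRCm38.p6, which served only for names, so no positions or lengths are printed. Rows with repeated identifiers (1395 rows of 410 identifiers) were left out, and the transcript with the most calls stood for its gene, a choice made after the tables were opened. This gave 23882 genes, of which 19826 had at least 500 calls in every library. Overlapping genes share calls, and members of families with similar sequence are uncertain.

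Groups were taken from the labels. Nothing in them says more of the replicates than that they are separate samples, so p-values measure the spread between these samples. No pair of libraries in a group agreed within sampling noise (chi-square per gene of 2.7 or more). In 4 libraries, 1 per group, coverage of the Y-linked genes Ddx3y, Kdm5d and Eif2s3y was low; 493 genes whose coverage there rose between 1.5 and 2.7 times are called X-like.

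Mean gene levels were compared with two-sided exact permutation tests. Per gene, a quasi-binomial logistic model with a mean per group was fitted to the calls of all 12 libraries, and its dispersion was moderated with limma 3.58.1 (squeezeVar, with trend and robust) in R 4.3.3. Benjamini-Hochberg adjusted p under 0.05 was the threshold, and effects are log2 odds ratios. The median overdispersion was 5.0. Gene lists fixed beforehand were tested on log2(percent + 0.1) with camera, at a preset correlation of 0.01 and an estimated one, and with fry. camera compares moderated t statistics, so noise within a list counts as well as the size of its change. The estimated correlation kept the shift of each library common to all genes, so it may be too high and its p-values too large. fry, which asks whether the genes of a list moved, on balance, one way, passed for 36 of 38 combinations of list and comparison, the exceptions being Hox genes at P40 and ribosomal protein genes at 4 months. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

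The gene model was tested on simulated calls for 19826 genes with 200 changed. With the spread the model assumes, the P40 comparison recovered 84.2% of genes raised by a factor of 2 and 57.4% of those lowered by it, and 5.4% of calls were false. If the biological spread is the same at every depth, 8.81% of the P40 calls were false. For the 4-month comparison the recovered shares were 29.2% and 5.21%, with 6.6% false, so few falls could be seen there. These shares hold where few genes change and libraries of a group do not differ by a shift common to all genes. Mean gene levels of the P40 miR29 knockout libraries ran from 1.72% to 2.46%. Such shifts were thus present, and the false share of the real calls was not measured. With all genes raised by a factor of 1.5 at P40 and 1.75 at 4 months, 80.1% and 62.5% were recovered.

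Named genes followed a rule set before the data were examined, as were the tests, lists and most alternatives. For each mutant it took up to 8 rises and 8 falls of largest size among genes past the threshold with non-overlapping libraries, a WT level of at least 0.5% and a proper symbol. It added the member of each list with the smallest p, and a fixed set of genes of the methylation machinery, of which Dnmt3a, Dnmt3b, Dnmt1, Tet1, Tet2 and Tet3 are given and the rest is not reported here. For the difference between mutants it took the 5 smallest p in each direction, and for age the 5 largest changes in each direction. Its length filter was not applied. Alternatives covered the scale, pseudocount, filters, centring, background subtraction, the replicate block, moderation and leaving out each library.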

Results

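Non-CG methylation (mCH), the methylation of cytosines that are not followed by guanine, was measured over genes in mouse cortex by whole-genome bisulfite sequencing in 12 libraries. In bisulfite sequencing an unmethylated cytosine is read as thymine, so each covered cytosine gives a methylated or an unmethylated call. At postnatal day 40 (P40) the labels gave 4 wild-type (WT) libraries and 4 libraries labelled miR29 knockout (KO). At 4 months they gave 2 WT libraries and 2 libraries labelled Dnmt3a mi5; Dnmt3a encodes a DNA methyltransferase, "mi5" is kept as the labels give it, and the sample titles of these libraries read DNMT3AmiR29MUT. Non-CG cytosine calls, methylated and unmethylated together, ranged over 23882 genes from 399563492 to 732985426 per library. Of these genes, 19826 had at least 500 calls in every library. In the first P40 WT library the tested genes together were 1.495% methylated (95% Wilson interval 1.494 to 1.496). Its median gene, with 14324 calls, had a level of 1.21% and an interval of 1.048 to 1.408 for a gene of that depth. The median gene had 11864 to 14324 calls in the P40 libraries and 6848 to 8384 at 4 months. These intervals cover counting error only.

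The first comparison asked whether mCH differed between the miR29 KO and WT cortex at P40. The 4 miR-29 genes, looked up after the tables were opened as a check of the labels, had 6 to 69 calls together in the KO libraries and 121 to 244 in WT (two-sided exact permutation test, p = 0.0286), while the median of 1104 other microRNA genes was 50 to 53 and 44 to 55 calls. Mir29a had 0 to 8 calls in the KO and 30 to 84 in WT, Mir29c 0 to 22 and 25 to 60, Mir29b-2 0 to 32 and 30 to 115, and Mir29b-1 0 to 22 and 8 to 32, so the ranges overlapped for the last 2. The labels do not say which of these genes the KO lacks or in which cells. At 4 months the genes together had 106 to 129 calls in mi5 and 151 to 200 in WT (exact permutation test, p = 0.333, the smallest possible), while the median of the other microRNA genes was also lower in mi5, 20 to 21 calls against 27 to 28. The mean gene level was 2.16% ± 0.316 (SD, n = 4) in the KO and 1.39% ± 0.124 (SD, n = 4) in WT, a difference of 0.770 points and a ratio of 1.56. Every KO library, from 1.72% to 2.46%, lay above every WT library, from 1.28% to 1.54% (two-sided exact permutation test, p = 0.0286, the smallest that 70 assignments allow). Of 19826 genes, 15167 rose and 9 fell past the threshold in the KO, with a median log2 odds ratio of 0.65. The log2 odds ratio was positive for 95.9% of genes, so a gene not past the threshold was not thereby unchanged. After each library was centred on its own median, which removes this common shift, 269 genes lay above the shift and 643 below it. In the 3 KO and 3 WT libraries with Y-gene coverage the ratio of means was 1.61, and it was 1.40 between the single KO and WT libraries with low Y-gene coverage.

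**Figure D1:**
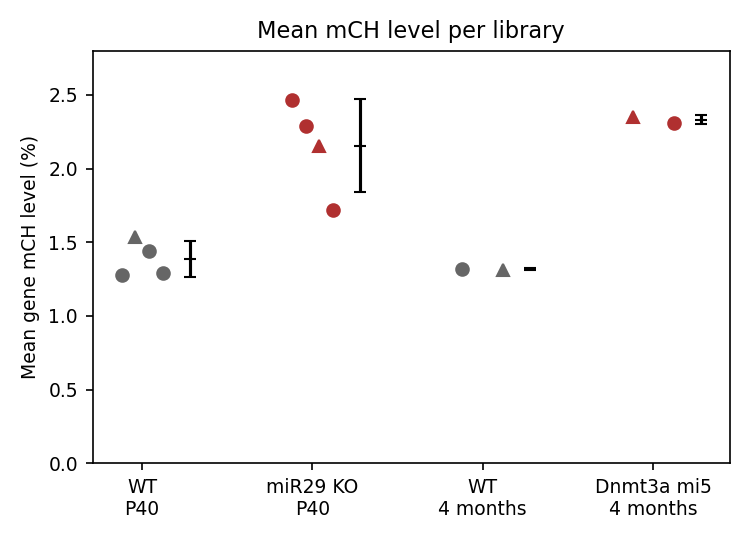
Mean gene mCH level in percent for each of the 12 libraries by group; grey symbols are WT, red symbols mutant, triangles are libraries with low coverage of Y-linked genes, and bars show the mean ± SD beside each group. All mutant libraries sit between 1.72% and 2.46%, above all WT libraries, which sit between 1.28% and 1.54%.

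Among genes chosen by a fixed rule for size of change, Serpina1c, a serine protease inhibitor of the liver, rose from 0.604% ± 0.202 to 1.80% ± 0.296 (SD, n = 4 each; log2 odds ratio 1.60, SE 0.23). Serpina1e rose from 1.01% to 2.65%. Reg2, a secreted protein of the pancreas, rose from 1.13% to 3.41%, and Tnni2, a fast skeletal muscle troponin, from 1.53% to 4.32%. The interferon-inducible Ifitm7 rose from 1.27% to 3.33%, Wfdc16 from 1.06% to 2.78%, the apolipoprotein gene Apoa2 from 0.639% to 1.62%, and the olfactory receptor gene Olfr1355 from 0.645% to 1.86%. These genes had between 1060 and 5992 mean calls per library. Serpina1c, Serpina1e, Reg2, Ifitm7 and Olfr1355 belong to families of similar sequence, so their calls are uncertain. Ube2m, a NEDD8-conjugating enzyme, was the gene named as the largest fall, from 0.928% ± 0.613 to 0.246% ± 0.0887 with 1586 mean calls. The other genes called as falling were Abhd17a, Coa4, Il3ra, Midn, Tpbpa, Tspyl2, Vmn1r3 and Zkscan14, named after their values were seen. Their WT levels lay between 0.578% and 1.10%, their KO levels between 0.295% and 0.438%. The mean 1st percentile of KO gene levels was 0.277%. WT and KO libraries overlapped in each of these genes. Ube2m separated only narrowly, with 0.348% in its lowest WT library and 0.344% in its highest KO library.

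Most markers of each cortical cell type rose in the KO. In the counts that follow, the count adjusted over the list alone stands in parentheses. Of all genes 76.5% rose past the threshold at P40, the share against which these counts are to be set. Of the excitatory neuron markers 12 (12) of 19 rose, of the inhibitory neuron markers 15 (15) of 21, of the astrocyte markers 16 (16) of 18 and of the microglia markers 14 (14) of 16. All 16 (16) oligodendrocyte lineage markers and all 15 (15) vascular markers rose. After centring, 4 excitatory neuron markers and 1 astrocyte marker lay below the common shift, and 1 oligodendrocyte lineage marker above it. The inhibitory neuron, microglia and vascular markers had 0 either way. Of all 19826 genes, 643 lay below the shift and 269 above it. Foxp2, a transcription factor of deep-layer neurons, went from 2.39% to 3.74%, and Reln, which encodes the secreted protein reelin, from 2.31% to 3.75%. The astrocyte enzyme gene Aldh1l1 went from 2.43% to 4.02%, the tight junction gene Cldn11 from 2.53% to 4.20%, the microglial receptor gene Cx3cr1 from 1.97% to 3.33% and the endothelial gene Pecam1 from 2.72% to 4.49%. By camera the vascular markers lay above other genes only with the preset correlation (adjusted p = 0.0151). With a correlation estimated at 0.69 the camera adjusted p was 0.84.

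Genes of neuronal function rose as well, as did most genes. The median log2 odds ratio was 0.56 for synaptic, 0.63 for ion channel and 0.69 for axon guidance genes, against 0.65 for all genes. Of the synaptic genes 28 (28) of 40 rose, including Cntnap2, a cell adhesion gene, from 1.80% to 3.02%. Of the voltage-gated ion channel genes 26 (26) of 29 rose, including the calcium channel gene Cacna1g from 1.40% to 2.60%. Of the axon guidance and migration genes 28 (28) of 29 rose, Robo1 from 2.17% to 3.54%, and of the collagen and matrix genes 20 (20) of 20, Adamts2 from 2.15% to 3.75%. By camera both lists lay above other genes only with the preset correlation (adjusted p = 0.00436 each). With correlations estimated at 0.85 and 0.86 the camera adjusted p was 0.84 each. No random lists matched on level were drawn for them. Of the neurodevelopmental disorder genes 17 (16) of 26 rose, and of genes of other organs 25 (25) of 29, with Cyp2e1, a liver cytochrome, at 1.71% and 3.33%. Of the immediate early genes 7 (7) of 17 rose, Nr4a3 from 1.996% to 3.35%. By camera the list lay below other genes only with the preset correlation (adjusted p = 0.0209, against adjusted p = 0.696 with an estimated correlation). Of the clustered protocadherin genes 32 (29) of 56 rose, Pcdhga12 from 0.948% to 1.46%, with a median log2 odds ratio of 0.44 (adjusted p = 3.8e-09; adjusted p = 0.696 with an estimated correlation). Of the olfactory receptor genes 76 (71) of 118 rose, Olfr56 from 1.83% to 3.20%. Their median log2 odds ratio of 0.74 lay above that of all genes while camera placed the list below other genes (adjusted p = 0.00436; adjusted p = 0.84 with an estimated correlation).

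Ribosomal protein, oxidative phosphorylation and Hox genes had lower log2 odds ratios than other genes in the KO. None of 21 ribosomal protein genes passed the test, 0 adjusted over the list alone. Rps6, which had the smallest p, had 0.344% ± 0.168 in WT and 0.657% ± 0.215 in the KO (n = 4 each, adjusted p = 0.0578); it passed without miR29KO_P40 replicate 1 (adjusted p = 0.0210) and without WT_P40 replicate 4 (adjusted p = 0.0295). Of the oxidative phosphorylation genes 5 (4) of 31 rose, the complex I genes Ndufs4, from 1.14% to 1.77%, Ndufa5 and Ndufb5, and Sdhc and Uqcrc2 of other complexes. Of the Hox genes, which pattern the body axis, 2 (0) of 29 rose, Hoxc9 and Hoxb5, the latter at 1.66% ± 0.487 and 2.81% ± 0.910. The Hoxb5 call was lost without WT_P40 replicate 1 or 4 and without miR29KO_P40 replicate 2 or 3, with adjusted p from 0.0537 to 0.108. The members of these 3 lists other than Rps6, Ndufs4 and Hoxb5 were named after their values were seen. Median WT levels of the lists were 0.389%, 0.455% and 0.363%. Their adjusted p was 1.7e-13, 3.3e-08 and 1.7e-21 with the preset correlation, and 2.9e-04, 0.00895 and 1.3e-04 with an estimated one. Across all genes the median log2 odds ratio was 0.24 in the lowest decile of the 4-month WT level. It reached 0.72 in the eighth decile and was 0.67 in the tenth. The 4-month WT libraries do not enter the P40 change. These deciles were chosen after those of the mean over all libraries were seen, where the lowest and eighth had medians of 0.20 and 0.73.

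**Figure D2:**
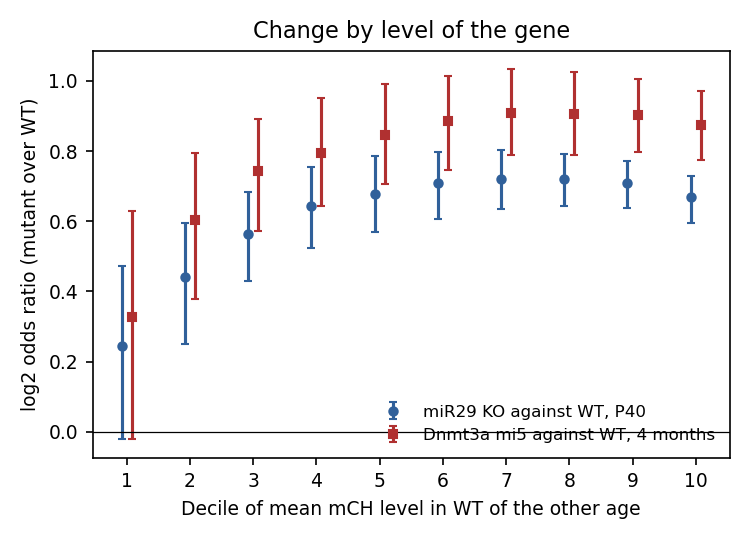
Median log2 odds ratio of mutant over WT (vertical axis) in each decile of the mean mCH level of WT at the other age (horizontal axis); circles are the P40 KO, squares the 4-month mi5 comparison, and bars span the quartiles over genes. The medians of the lowest decile are 0.24 and 0.33, those of the eighth 0.72 and 0.91.

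Genes of the methylation machinery were followed in every comparison. At P40 Dnmt3a itself rose from 0.736% ± 0.0421 to 0.995% ± 0.105 (n = 4 each; adjusted p = 0.0132), a log2 odds ratio of 0.44; after centring it was -0.23 and did not pass (adjusted p = 0.0597). Dnmt3b rose from 2.51% to 4.09%, the maintenance methyltransferase gene Dnmt1 from 0.859% to 1.34%, and the 5-methylcytosine oxidase genes Tet1 from 1.43% to 2.69%, Tet2 from 1.20% to 1.88% and Tet3 from 0.851% to 1.28%. In all, 12 (12) of 18 genes of this list rose. The gene-level p-values come from a quasi-binomial model with limma-moderated dispersion.

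The second comparison asked the same of the Dnmt3a mi5 allele at 4 months. The mean gene level was 2.33% ± 0.0306 (SD, n = 2) in the mutant and 1.32% ± 0.00564 (SD, n = 2) in WT, a difference of 1.01 points and a ratio of 1.77. Both mutant libraries lay above both WT libraries, but an exact permutation test of 2 against 2 cannot go below the p = 0.333 found. Of 19826 genes 11649 rose and 0 fell past the threshold in the quasi-binomial model with limma-moderated dispersion, and 12857 had an unadjusted p under 0.05. The median log2 odds ratio was 0.83, and 95.9% of genes had a positive one. By limma on percent levels 14339 genes rose and 33 fell. After centring, 0 genes lay above the common shift and 7 below it, with 1833 at an unadjusted p under 0.05. The count was 4679 without WT_4mo replicate 1, 6310 without WT_4mo replicate 2 and 7713 without Dnmt3a_mi5_4mo replicate 1.

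The genes named as the largest rises at 4 months had few calls, 1108 to 3269 on average. Cck, which encodes the neuropeptide cholecystokinin, rose from 0.701% ± 0.458 to 3.08% ± 0.632 (SD, n = 2 each; log2 odds ratio 2.14, SE 0.51). Nrarp, a Notch pathway gene, rose from 0.958% to 4.72%, Sbpl from 1.13% to 5.16%, the transporter gene Slc16a13 from 0.561% to 2.71% and the kallikrein family gene Klk1b9 from 0.848% to 3.51%. Lce1h, Tmem253 and Fgfbp3 reached 4.06%, 3.17% and 2.54% in the mutant from 0.809%, 0.697% and 0.552%. Without WT_4mo replicate 1 the calls of Nrarp, Sbpl, Lce1h, Tmem253 and Fgfbp3 were lost, with adjusted p from 0.0520 to 0.136; those of Lce1h, Tmem253 and Fgfbp3 were also lost without WT_4mo replicate 2, and those of Tmem253 and Fgfbp3 without Dnmt3a_mi5_4mo replicate 1, with adjusted p from 0.0568 to 0.112. Cck, Slc16a13 and Klk1b9 passed whichever single library was left out. Klk1b9 and Sbpl have close relatives in the genome, so their calls are uncertain.

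Cell type markers rose in the mi5 cortex too, where 58.8% of all genes rose past the threshold. Of the excitatory neuron markers 11 (11) of 19 rose, of the inhibitory 12 (12) of 21, of the astrocyte 14 (14) of 18, of the oligodendrocyte lineage 12 (12) of 16, of the microglia 11 (11) of 16 and of the vascular markers 14 (15) of 15. Etv1 went from 2.29% to 4.15%, Prox1 from 2.75% to 4.74%, Aldh1l1 from 2.23% to 4.54%, the myelin gene Mobp from 1.45% to 3.30%, the microglial receptor gene P2ry12 from 2.07% to 3.82% and the endothelial receptor gene Kdr from 2.46% to 4.67%. Of the synaptic genes 29 (31) of 40 rose, Cntnap2 from 1.58% to 3.10%, and of the ion channel genes 23 (24) of 29, the potassium channel gene Kcnh7 from 1.01% to 2.13%. Of the neurodevelopmental disorder genes 12 (12) of 26 rose, Zeb2 from 0.885% to 2.16%, of the immediate early genes 6 (6) of 17, Bdnf from 1.92% to 3.26%, and of genes of other organs 23 (24) of 29, the keratin gene Krt14 from 1.16% to 4.19%. Of the axon guidance genes 28 (28) of 29 rose, Efna5 from 2.05% to 3.82%, and of the collagen and matrix genes 19 (19) of 20, Col3a1 from 1.60% to 3.17%. By camera both lists lay above other genes only with the preset correlation (adjusted p = 0.0146 and 0.0184, against adjusted p = 0.85 for both with an estimated correlation).

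The lists with the lowest log2 odds ratios at P40 were also low at 4 months. None of 21 ribosomal protein genes passed, 0 adjusted over the list alone, and their median log2 odds ratio was -0.09; Rps6 had 0.815% ± 0.271 in WT and 0.343% ± 0.0399 in the mutant (n = 2 each, adjusted p = 0.236). Of the oxidative phosphorylation genes 3 (1) of 31 rose, Ndufs4 from 1.15% to 2.28%, Ndufb5 and Sdhc, and of the Hox genes 4 (0) of 29, Hoxa9, from 2.63% to 5.32%, Hoxc5, Hoxc13 and Hoxd13. All but Ndufs4 and Hoxa9 were named after their values were seen. The 3 lists lay below other genes with an adjusted p of 1.4e-04, 0.00964 and 5.4e-04, each with an estimated correlation. Of the olfactory receptor genes 24 (3) of 118 rose, Olfr330 from 1.06% to 3.58%, and of the clustered protocadherin genes 21 (0) of 56, Pcdhac1 from 0.860% to 1.57%. Both lists had lower median log2 odds ratios, 0.75 and 0.66 against 0.83 for all genes. By camera both lay below other genes only with the preset correlation (adjusted p = 4.0e-06 and 1.6e-05, against adjusted p = 0.85 for both with an estimated correlation). The Hoxa9 call was lost without WT_4mo replicate 1 (adjusted p = 0.106) and without Dnmt3a_mi5_4mo replicate 2 (adjusted p = 0.0564), and that of Pcdhac1 without WT_4mo replicate 1 or 2 or Dnmt3a_mi5_4mo replicate 1 (adjusted p = 0.0527 to 0.0917).

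**Figure D3:**
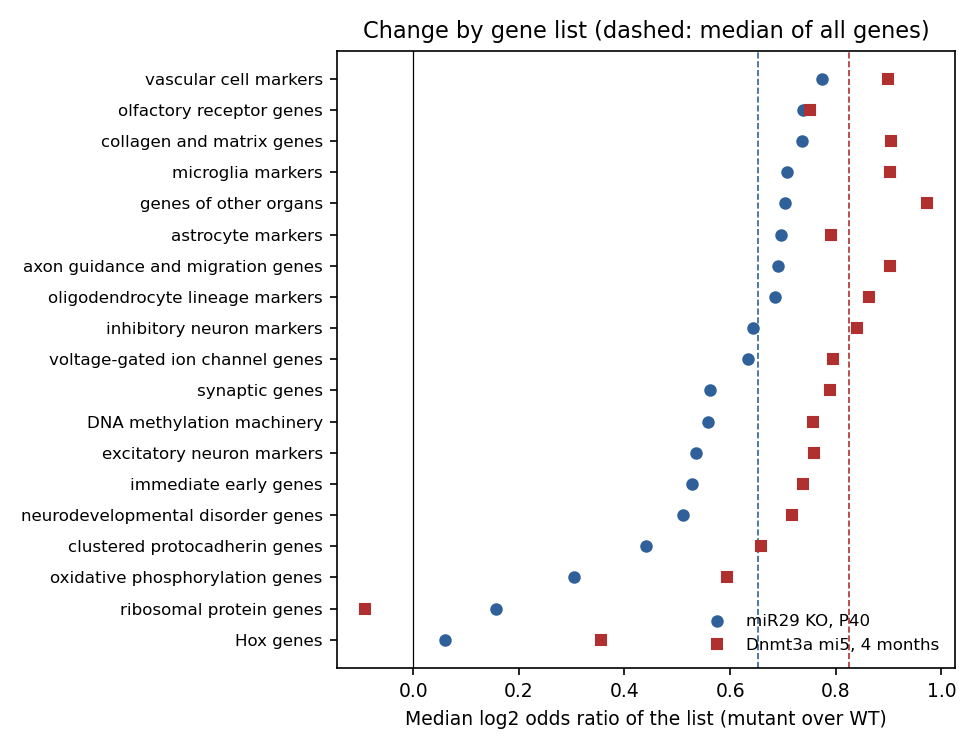
Median log2 odds ratio of mutant over WT (horizontal axis) for each fixed gene list; circles are the P40 KO, squares the 4-month mi5 comparison, and dashed lines the medians of all genes, 0.65 and 0.83. Hox genes lie at 0.06 and 0.36, ribosomal protein genes at 0.16 and -0.09.

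Of the methylation machinery 8 (8) of 18 genes rose in the mi5 cortex. Dnmt3a had 0.672% ± 0.00485 in WT and 1.10% ± 0.0676 in the mutant (n = 2 each; adjusted p = 0.0540). Dnmt3b rose from 2.22% to 3.86%, Dnmt1 from 0.775% to 1.46%, Tet1 from 1.53% to 2.63%, Tet2 from 1.18% to 2.03% and Mbd5, which encodes a methyl-CpG binding domain protein, from 0.899% to 1.73%. Tet3 had 0.864% and 1.22% (adjusted p = 0.120). The calls of Dnmt3b, Dnmt1, Tet1, Tet2 and Mbd5 were lost without WT_4mo replicate 1, those of Dnmt3b, Dnmt1, Tet1 and Tet2 also without replicate 2, those of Dnmt1 and Tet1 without Dnmt3a_mi5_4mo replicate 1, and those of Dnmt3b, Dnmt1 and Tet1 without its replicate 2, with adjusted p from 0.0523 to 0.143. Without miR29KO_P40 replicate 4, which enters through the shared spread, Dnmt3a (adjusted p = 0.00675) and Tet3 (adjusted p = 0.0257) passed, and Dnmt3a also without its replicate 1 (adjusted p = 0.0421).

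The changes of both mutants were then compared. Across 19826 genes, which are not independent replicates, the log2 odds ratios correlated with a Pearson r of 0.41 and a Spearman rho of 0.39. The Pearson r ran from 0.27, with the 1st percentile subtracted or no minimum of calls, to 0.81 by limma on percent levels. Of all genes 94.4% had the same sign, where independent signs would give 92.1%; the comparisons had separate WT libraries. In both comparisons 11250 genes rose, where independent lists of these sizes would share 8912. Both tests used the same estimate of spread for a gene and favoured genes with many calls. Of genes with at least 20000 calls on average, 94.7% changed at P40 and 89.3% at 4 months. The excess over 8912 therefore says little about shared changes. The test of the difference itself called 0 genes in the quasi-binomial model with limma-moderated dispersion, 289 at an unadjusted p under 0.05, and 3 by limma on percent levels, Mup13, Pate9 and Reep2, of which Pate9 and Reep2 were named after their values were seen. Among the named genes the smallest p values were those of Mup13, with log2 odds ratios of -0.18 at P40 and 2.48 at 4 months, Cd34 with 0.29 and 1.16, and Fut7 with 0.90 and -1.14 (adjusted p = 0.998 each). Mup13 had 0.242% in the 4-month WT, near the mean 1st percentile of gene levels there, 0.228%. Fut7 had 1.20% ± 1.16 (SD, n = 2) in mi5. Mutation and age differed together between the comparisons.

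The last comparison was between WT cortex at 4 months and at P40, where age and cohort change together. Mean gene levels were 1.32% and 1.39%, a difference within the spread of the P40 libraries (exact permutation test, p = 0.800; the smallest possible is 0.133). In this background 26 genes were higher at 4 months and 0 lower in the model with limma-moderated dispersion, and 462 had an unadjusted p under 0.05; limma on log2(percent + 0.1) called 26 higher and 6 lower. Atp6v1d, a subunit gene of the vacuolar proton pump, went from 0.563% ± 0.142 (n = 4) to 2.58% ± 0.155 (n = 2). Prr36 went from 0.902% to 4.04%, Spata33 from 1.19% to 4.55% and the folate enzyme gene Fpgs from 1.71% to 5.62%. Uba1, a ubiquitin-activating enzyme gene, went from 2.13% to 8.80% on its transcript with the most calls, and did not pass on that with the fewest calls, nor without WT_P40 replicate 1 (adjusted p = 0.0792) or miR29KO_P40 replicate 4 (adjusted p = 0.123). The number of genes was 42 without miR29KO_P40 replicate 4, which enters through the shared spread, 312 after centring, 288 higher and 24 lower, 11 without trend and robust moderation, and 1 among genes with at least 20000 calls.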

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

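The tests of conversion, neuron share, depth and cohort, and the count of splits, were chosen after the results were seen; the tests of gene lists against matched random lists were fixed before them. In 84 groups of 4 values, 1 library stood far from the others: Tnni2 in WT_P40 replicate 4 had 1.21%, while the others lay between 1.60% and 1.67%. Chance alone marks about 1 group in 20.

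The rise of mCH in both mutants was the main pattern. Of the 35 splits of the 8 P40 libraries into 4 and 4, only 1, the real one, changed as many genes, 15176. The highest other split changed 13209 and exchanges miR29KO_P40 replicate 4, the lowest KO library, with WT_P40 replicate 2, the highest WT library. All KO libraries lay above all WT libraries in mean level, so the real split was bound to rank near the top. The count thus repeats the permutation test of the means at its smallest p and adds no separate evidence against chance. The 4-month groups are too small for such a count. Incomplete conversion would add similar points to every gene, but the 1st percentile of gene levels rose by at most 4.62% of the rise of the median. A larger share of neurons could raise all genes by one factor if neurons held the mCH, and the medians of the 6 cell type marker lists would then agree within 0.1 in log2 odds ratio. They spanned 0.24 at P40 and 0.14 at 4 months, beyond that limit. The smallest camera adjusted p of these lists against other genes was 0.84 with correlations estimated at 0.37 to 0.69. Those estimates kept the shift of each library common to all genes, so this large p could not decide. Hox genes rose less than other genes (median 0.06 against 0.65 at P40, camera adjusted p = 1.3e-04 with an estimated correlation). They also lay below random lists matched on WT level and calls (0.42 at P40, and 0.36 against 0.66 at 4 months). Their median WT level at P40, 0.363%, was near the mean 1st percentile of gene levels there, 0.241%. A background of unconverted calls would shrink a common factor at such levels, and the matching shared WT libraries with the change. Hox genes therefore do not decide on one factor. A larger share of neurons that raised each gene by its own difference between cell types cannot be told apart from an effect of genotype, since levels per cell type are missing.

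The 26 genes higher in WT at 4 months were a second pattern. In 25 of them both mi5 libraries also lay above all 4 miR29 KO libraries, against 17.3% of all genes, which argues against noise of the shallower 4-month libraries. The excess at 4 months was 1.04 times as large in the mutants as in WT (95% bootstrap interval 0.82 to 1.23), as a fixed difference between cohorts, such as a sequence variant or read processing, might give. This ratio is biased low, because the genes were chosen by the WT excess: over the 53 genes chosen by the mutants' own difference it was 1.72 (1.40 to 2.16), biased high. The selection decides the value, so neither a cohort difference nor a gain acting as in other genes could be excluded, and age stays open, since age and cohort coincide.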

How the results depend on the processing

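The Y-coverage covariate, removal of X-like genes, the transcript with the fewest calls, the limit of 20000 calls and, for gene lists, the subtraction of the 1st percentile were chosen after the data were seen; limits on gene length and length-weighted means were not run, since lengths of the build used were not analysed here. Both means kept their direction throughout. Leaving out 1 library gave differences of 0.668 to 0.915 points at P40 and 0.993 to 1.04 at 4 months; the P40 test then misses the threshold because 35 assignments allow no p under it. Same-numbered libraries showed no clear pairing at P40. Correlations of their deviations ran from -0.054 to 0.109, those of other-numbered libraries from -0.136 to 0.206, which cannot exclude pairing. At 4 months, with 2 libraries per group, the sizes of these correlations are equal by construction (-0.089 for same numbers) and decide nothing. With the replicate numbers as a block the P40 difference was 0.770 (exact sign-flip p = 0.125, the smallest possible), and 15253 and 12341 genes changed. The block also took axon guidance genes at 4 months to adjusted p = 0.0503 and olfactory receptor genes at P40 to 0.0618. P40 counts ranged from 13868 to 16013 without 1 library, 4-month counts from 4679 to 13329 (4679 and 6310 without WT_4mo replicates 1 and 2, 7713 without Dnmt3a_mi5_4mo replicate 1), those for age from 18 to 42, and the correlation from 0.34 to 0.42. A lone library is there assumed to vary like the other groups.

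Centring each library gave 912 genes at P40, 7 at 4 months and 312 for age; it removes the common shift of 0.65 and 0.83 by construction. It turned the log2 odds ratio at P40 to -0.00198 for Foxp2, -0.0203 for Ndufs4, -0.0356 for Pcdhga12, -0.235 for Dnmt3a, -0.0236 for Dnmt1, -0.00984 for Tet2 and -0.0764 for Tet3, and at 4 months to -0.0381 for Prox1, -0.0763 for Bdnf, -0.0280 for Dnmt3b, -0.0660 for Tet1 and -0.0599 for Tet2, none past the threshold. With at least 20000 calls, fewer genes were tested and 6168, 5814 and 1 changed at P40, at 4 months and for age (Ppp6r2, named after its value was seen). The age count was 41 with only the WT libraries and 11 without trend and robust moderation, and limma on percent called 3 genes for the difference between mutants; the cause was not tested. The correlation was 0.81 for limma on percent, 0.60 with a pseudocount of 0.5, 0.32 at a mean level of at least 0.5%, 0.27 with the 1st percentile subtracted, 0.51 from 2000 calls, 0.27 with no minimum and 0.63 from 20000 calls; the cause was not tested. Of 16 calls of gene lists, 6 held with an estimated correlation, and fry, which asks another question, gave 36. Of the named genes' values in other settings, 1130 kept direction and side, 12 turned, 50 fell below and 32 passed the threshold; without 1 library 941 kept both, 35 fell below and 8 passed. Depth limits genes of few calls.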

Other observations

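The X-like genes had less mCH than other genes in the 4 libraries with low Y-gene coverage. Their level was 0.577 ± 0.0229 (SD, n = 4) of that of other genes there and 0.926 ± 0.0151 (SD, n = 8) in the rest (two-sided exact permutation within groups, p = 0.0156, the smallest that 64 assignments allow). In WT at P40 this was 1.07% of X-like calls in replicate 2 against 1.37% to 1.56% in the others, and in mi5 at 4 months 1.57% against 2.53%. The mutants' rise appeared in both kinds of library. The genes with the highest mean mCH over the 12 libraries were the protease gene Prss29, the liver receptor gene Asgr1 and Agmat, all among the 26 genes higher in WT at 4 months. Prss29 had 6.35% in WT at P40, 9.05% in the KO, 15.9% in WT at 4 months and 18.9% in the mi5 cortex.

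Low level and few calls may account for part of the low log2 odds ratios of the lists of ribosomal protein, oxidative phosphorylation and Hox genes; each was set against 10000 random lists matched on WT level and calls, a test fixed before its result was seen. The oxidative phosphorylation genes lay at percentile 8.49 in the KO and 48.2 in mi5, within the matched range. The ribosomal protein genes lay at percentile 9.28 in the KO, also within it, but at 0.09 in mi5, with a median of -0.09 against 0.49 in matched lists. The Hox genes lay below the range in both, at percentiles 0.01 and 1.08, with medians of 0.06 against 0.42 and 0.36 against 0.66. The lists were matched on the same WT libraries that enter the change. Genes low there by noise then seem to rise, which can lift the medians of matched lists. Whether level and calls give the whole difference for Hox genes, and for ribosomal protein genes in mi5, therefore could not be told. With the 1st percentile subtracted as background, camera at the preset correlation still placed the ribosomal protein, oxidative phosphorylation and Hox lists below other genes. The camera adjusted p was 3.9e-14, 6.3e-09 and 4.4e-23 at P40, and 3.0e-19, 2.0e-08 and 1.0e-12 at 4 months. Noise near the background also lowers the statistics that camera compares, so a background was not excluded. No other explanation was tested.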
